A study of Saccharomyces cerevisiae with 72 samples.

How the data were processed

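The study sequenced the genomes of diploid Saccharomyces cerevisiae isolates that had been passaged so that mutations accumulated. At each passage a line was taken through a single-colony bottleneck. The labels name 72 isolates by the genotype of a replicative DNA polymerase and of mismatch repair (MMR), and by the number of passages. Of these, 52 had accumulated mutations over 17 to 31 labelled passages, 19 had 1 passage, and 1 had no passage number. A single wild-type isolate was also sequenced after micrococcal nuclease digestion, which cuts DNA between nucleosomes.

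The authors deposited 1 list of variants for all isolates together. Its read values are counts, deposited by the authors with no normalization: whole numbers of reads that covered a site and of reads with each listed allele. The deposited allele frequencies are in percent, and they equalled 100 times the allele's reads over the coverage within 0.005. Each deposited variant has a position in bp on the authors' own reference, which is not the current public assembly, so coordinates below refer to the authors' reference. The deposited nucleosome list gives the first base, last base and centre of 44503 nucleosomes as a position in bp, and the deposited annotation gives features as a position in bp on the same sequence names. The labels name CASAVA 1.8 and Bowtie 0.12.8 without a role. The variant caller, the nucleosome caller and their settings were not given.

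The list holds 42799 variants. Of these, 36887 were substitutions, 5910 were insertions or deletions and 3 were calls with 2 new alleles, 1 of which is also counted among the insertions or deletions. The 1-base deletions numbered 4900 and the 1-base insertions 644, while 365 insertions or deletions spanned 2 or more bases, up to 8 bp. Coverage at listed variants was 20 or above, with a median of 229, and the percent of the second allele was 25 or above, so the authors' list had been filtered on both. The median coverage of an isolate's variants lay between 45.5 and 564.5. Depth at sites without a variant is not in the files, so missed variants could not be counted. A variant counted as homozygous when it had a single listed allele in at least 75 percent of the reads. There were 41098 distinct variants, of which 1223 were listed in more than 1 isolate. The 3 mitochondrial variants were left out of the tests by position.

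Percentages were printed with 8 decimals for 13 isolates and with 2 decimals for 39, which were treated as 2 processing sets. The 8-decimal set held all 5 wild-type msh2- isolates, 5 of the 7 pol1-L868M msh2- isolates and 3 of the 4 pol3-L612M msh2- isolates, and no MMR-proficient isolate. Coverage also fell with chromosome length in the 8-decimal set. The slope of log2 coverage at listed variants on log2 chromosome length was -0.569 to -0.0797 there, and -0.569 to -0.198 in the wild-type msh2- isolates, against which the altered polymerases were compared. It was -0.0782 to 0.0209 in the isolates of the 2-decimal set with at least 50 variants.

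Mutations were counted per isolate and divided by the labelled passages. Groups were compared by the mean of log2 mutations per passage, with isolates as replicates, by exact two-sided permutation tests. Folds are geometric means, and SE is the standard error of the log2 difference. Differences between polymerases in the fold on MMR loss were tested by permuting the residuals of an additive model, with 100000 resamples. The 9 mutation classes were the 6 base-pair substitutions, 1-base deletions, 1-base insertions and all other events. A pseudocount of 1 mutation per isolate was added before log2 for class rates and for insertions and deletions. A fold against a group with no mutation used a floor of 3 mutations over the group. P-values were adjusted by Benjamini-Hochberg within each family of comparisons, with a threshold of 0.05.

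Strand asymmetry was measured for each isolate as a log2 odds ratio. It compares the substitution of a purine with its complement, both read on the reference strand, to the right against to the left of the nearest of 274 annotated origin midpoints, with 0.5 added to each cell. A positive value means that the purine form is relatively more frequent to the right. Nucleosome density compared the core, within 73 bp of a nucleosome centre, with the linker, beyond that and up to 250 bp. Coding density compared annotated coding sequence with the rest of the 12055736 bp of the 16 nuclear chromosomes. Sign-flip tests were exact below 10 isolates and used 100000 resamples at 10 or more.

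Each of 5860 protein-coding genes was tested for more mutations than its share of coding length predicts, pooled over isolates, by a one-sided exact binomial test. Fixed lists of genes were tested by a two-sided exact binomial test. They covered replication polymerases, mismatch repair, checkpoint, cyclic AMP and RAS signalling, cell wall proteins with internal repeats, reporter and marker genes, chromatin remodelling and large genes. The annotation held 87 of their 88 members, and URA3 was absent. The rule for named genes took, per MMR state and kind of mutation, up to 10 genes with the smallest adjusted p that were hit in at least 3 isolates. It added the 4 members of each list with the most mutations and the targeted genes POL1, POL2, POL3, MSH2, MSH3 and MSH6. Intervals are 95 percent, Wilson for shares and exact for ratios of counts, and they cover counting error only.

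The design, lists, tests and most alternatives were fixed before the data were examined. The alternatives changed the denominator, the kinds of mutation, variants shared between isolates, clustered variants, pseudocounts, distances to origins, the core width, the linker limit and the annotated regions, and left out each isolate in turn. Tests of the processing sets, of depth, of related isolates, of all MMR-deficient isolates together and of the cell wall list without 4 members were added after the data were seen. So were the joint tests over 6 asymmetry classes and over the 3 present in every msh2- isolate, and the asymmetry comparisons that involve pol1-L868M.

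Tests were checked on simulated data. In the gene test for substitutions of MMR-deficient isolates, 56 percent of genes raised 4-fold and 2 percent of genes raised 2-fold were called, with 0 false calls. The permutation test of 4 against 5 isolates detected a simulated 2-fold difference in 69.8 percent of draws. That share holds only for a single test and for the spread set in the simulation. It does not give the power of the adjusted comparisons of real groups, whose spread can be wider. Wild-type msh2- isolates, for example, ranged from 3.48 to 12.7 mutations per passage. Run lengths of homopolymers were not analysed because the files give no genome sequence, and base composition was not controlled for the same reason. The list holds 0 variants for the 1-passage isolates, so no background could be subtracted. The computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.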

Results

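Budding yeast copies its nuclear genome with DNA polymerases alpha, epsilon and delta, whose catalytic subunits are encoded by POL1, POL2 and POL3. The isolates carried either wild-type polymerases or 1 altered form: pol1-L868M, pol2-M644G or pol3-L612M, each an amino acid change in the active site that lowers copying fidelity. MMR removes mismatches left by replication. Msh2 is needed for mismatch recognition with either of its partners, Msh3 and Msh6, and it was absent in msh2- isolates, whereas both partners were absent in msh3- msh6- isolates. The design lets mutations made by each polymerase be compared with and without their removal.

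Among MMR-proficient isolates that had accumulated mutations there were 8 with wild-type polymerases, 6 pol1-L868M, 8 pol2-M644G and 8 pol3-L612M. Among msh2- isolates there were 5 with wild-type polymerases, 7 pol1-L868M, 4 pol2-M644G and 4 pol3-L612M, and 2 further pol2-M644G isolates were msh3- msh6-. All MMR-proficient isolates had 31 labelled passages, and MMR-deficient isolates had 17 to 31. The number of mutations that an isolate carried sets the precision of its values. It lay between 1 and 7 in MMR-proficient wild-type isolates, and between 11 and 57 in those with an altered polymerase. In msh2- isolates it lay between 80 and 393 with wild-type polymerases and between 794 and 4828 with an altered polymerase. The 1-passage isolates listed 0 variants, so the files give no measured background.

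With MMR intact, each altered polymerase raised the mutation rate. Wild-type isolates gained 0.117 ± 0.054 mutations per passage (SD, n = 8), and pol1-L868M isolates gained 0.462 ± 0.109 (SD, n = 6), 4.33-fold more. The rates of pol2-M644G at 1.23 ± 0.366 (SD, n = 8) and of pol3-L612M at 1.22 ± 0.195 (SD, n = 8) were 11.3-fold and 11.5-fold above wild type. On the log2 scale the increases were 2.11 ± 0.31 (SE) for pol1-L868M, 3.50 ± 0.32 for pol2-M644G and 3.53 ± 0.29 for pol3-L612M. Adjusted exact permutation p-values were 0.000333, 0.000233 and 0.000233 over 3 comparisons, and the raw values were the smallest that these group sizes can give. Almost all of these mutations were substitutions: insertions and deletions numbered 0 in wild type, 0 in pol1-L868M, 6 in pol2-M644G and 4 in pol3-L612M.

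The pol3-L612M isolates in this comparison were not all independent. Replicates 6 and 7 shared 37 substitutions, 86.0% of those in replicate 6, and replicate 2 shared 23 with replicate 7 and 21 with replicate 6. Replicates 1 and 3 shared 8. The 3 isolates that shared most were then averaged and counted as 1. The comparisons of total rates that use MMR-proficient pol3-L612M isolates kept their direction and their side of the threshold. Differences in the other comparisons do not involve these isolates and could not change. Fewer substitutions were shared in 2 further groups: 135 between the 2 pol2-M644G msh3- msh6- isolates, 7.01% of those in the smaller, and 35 between replicates 6 and 7 of the pol1-L868M msh2- isolates, 3.71%. These isolates were counted as separate, and the total rates kept their direction and their side of the threshold when replicate 6 or 7 was left out.

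Loss of Msh2 raised the mutation rate of every polymerase genotype by well over an order of magnitude. The rates per passage in msh2- isolates were 8.77 ± 4.17 (SD, n = 5) with wild-type polymerases, 66.2 ± 43.4 (SD, n = 7) in pol1-L868M, 90.9 ± 13.2 (SD, n = 4) in pol2-M644G and 148.9 ± 33.8 (SD, n = 4) in pol3-L612M. Against the MMR-proficient isolates of the same polymerase these were 74.7-fold, 126-fold, 76.3-fold and 121-fold higher. The log2 differences were 6.22 ± 0.47 (SE), 6.98 ± 0.34, 6.25 ± 0.19 and 6.92 ± 0.19, with adjusted exact permutation p-values of 0.00155, 0.00155, 0.00202 and 0.00202 over 4 comparisons. Within 1 processing set the difference was 6.69 in pol1-L868M, with 2 msh2- isolates and an adjusted exact permutation p of 0.0536, and 6.88 in pol3-L612M, with 1 msh2- isolate. The raw value for pol1-L868M was the smallest that these group sizes can give. For wild-type polymerases, the processing set and MMR status cannot be told apart.

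Without Msh2, each altered polymerase also had a higher rate than wild type. Against msh2- isolates with wild-type polymerases, rates were 7.30-fold higher in pol1-L868M (log2 2.87 ± 0.48, SE), 11.5-fold in pol2-M644G (3.53 ± 0.39) and 18.7-fold in pol3-L612M (4.22 ± 0.41). Adjusted exact permutation p-values were 0.00379, 0.00794 and 0.00794, and the raw values were the smallest possible. Within 1 processing set, the log2 differences were 2.98 for pol1-L868M and 4.24 for pol3-L612M. All pol2-M644G isolates and all wild-type msh2- isolates were in different sets, so for this pair the set and the group cannot be told apart.

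Substitutions and insertions or deletions behaved differently on loss of Msh2. In wild-type polymerase isolates the substitution rate rose 14.5-fold, against 110-fold in pol1-L868M, 69.0-fold in pol2-M644G and 106-fold in pol3-L612M. These folds on MMR loss differed from wild type by 2.93, 2.25 and 2.86 on the log2 scale, with adjusted permutation p-values of 0.000135, 0.00096 and 0.000135. With the processing set as a term, the differences were 3.06 for pol1-L868M and 2.88 for pol3-L612M. This term rests on the 2 pol1-L868M and the 1 pol3-L612M msh2- isolates of the 2-decimal set. All pol2-M644G isolates were in another set than all wild-type msh2- isolates. For the pol2-M644G difference in fold, the set and the group therefore cannot be told apart. For all mutations together the corresponding differences were 0.75, 0.03 and 0.70, with adjusted permutation p-values of 0.286, 0.956 and 0.286, so a difference was not detectable there. With variants listed in 1 isolate only, that of pol3-L612M was 2.53, at an adjusted permutation p of 0.0315. This setting drops the substitutions shared by related MMR-proficient pol3-L612M isolates.

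Insertions and deletions were the main product of MMR loss in wild-type polymerase isolates. They reached 6.84 ± 2.93 per passage (SD, n = 5) there, beside 1.93 ± 1.30 substitutions. Against the 0 listed in MMR-proficient wild-type isolates this was at least 583-fold higher, and in pol1-L868M it was at least 393-fold higher. In pol2-M644G the pooled rate rose 430-fold (95% interval 197 to 1173) and in pol3-L612M 1264-fold (492.8 to 4643). Among msh2- isolates, rates of insertions and deletions were 1.00-fold wild type in pol1-L868M, 1.55-fold in pol2-M644G and 3.26-fold in pol3-L612M, with adjusted exact permutation p-values of 0.989, 0.333 and 0.0238. Most 1-base deletions removed an A or a T: 98.9% in wild type, 94.3% in pol1-L868M, 95.3% in pol2-M644G and 87.6% in pol3-L612M.

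**Figure D1:**
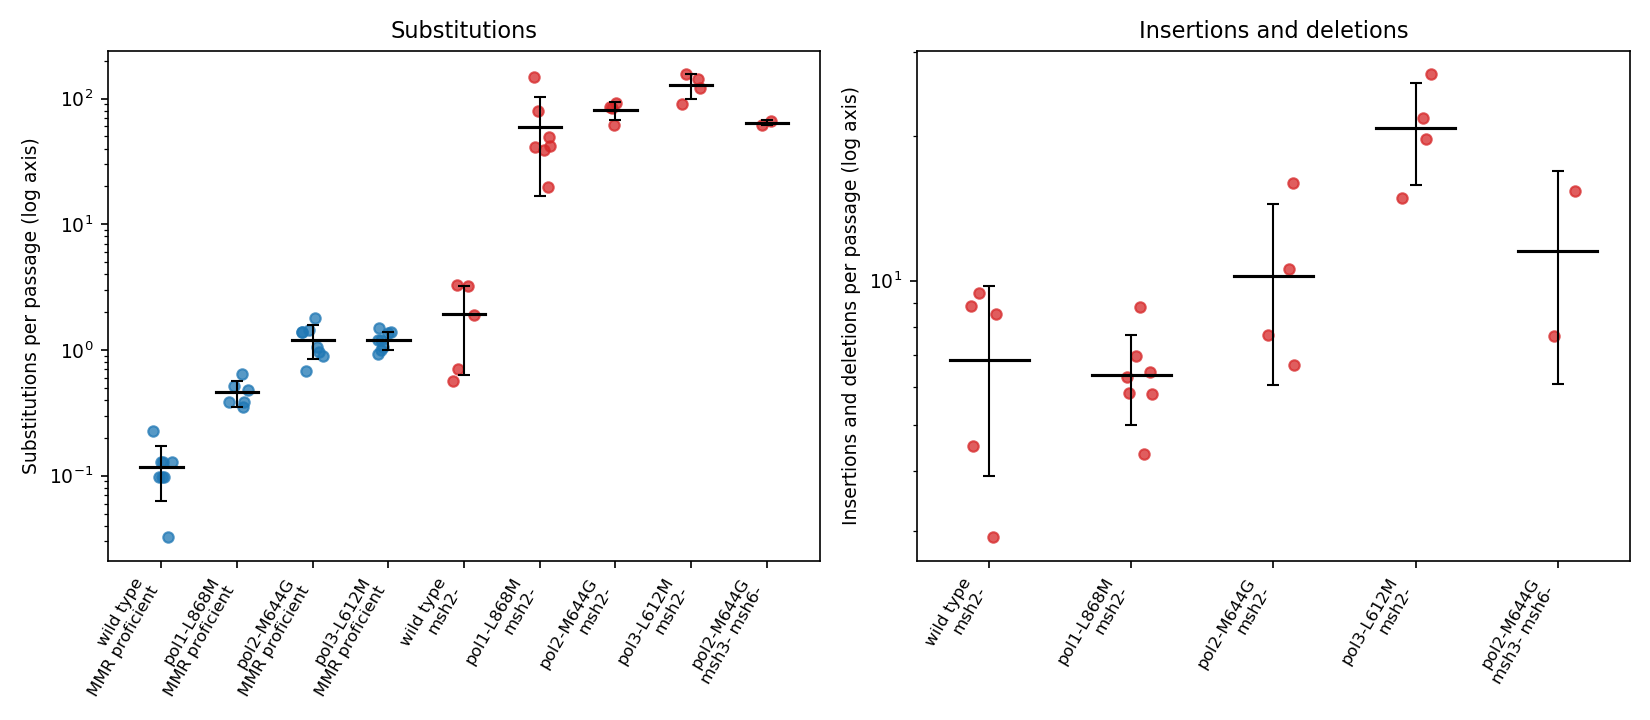
Substitutions per passage in 9 groups and insertions and deletions per passage in the 5 MMR-deficient groups, both on log axes; points are isolates, horizontal lines are means and bars are SD. Mean substitution rates in msh2- isolates run from 1.93 with wild-type polymerases to 128.0 in pol3-L612M, whereas mean rates of insertions and deletions run from 6.36 in pol1-L868M to 20.9 in pol3-L612M.

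The pol2-M644G isolates without Msh3 and Msh6 were too few to be told apart from those without Msh2 by these tests. Their rate was 75.8 ± 8.42 per passage (SD, n = 2) against 90.9 ± 13.2 (SD, n = 4), a log2 difference of -0.25 ± 0.16 (SE). The exact permutation p was 0.333, and 2 against 4 isolates cannot go below 0.0667. None of the 9 mutation classes passed, although at 0.05 no class could have.

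With MMR intact, the spectrum of pol2-M644G differed from that of wild type. In pol2-M644G, A:T to T:A made up 63.1% ± 7.38 of an isolate's mutations (SD, n = 8), against 11.2% ± 18.3 in wild type (SD, n = 8), with an adjusted exact permutation p of 0.00952. In pol3-L612M, A:T to G:C made up 51.8% ± 5.83 and G:C to A:T 30.6% ± 6.09 (SD, n = 8), at adjusted exact permutation p-values of 0.0804 and 0.122 against wild type. The shares of A:T to G:C and G:C to A:T in pol1-L868M were 28.1% ± 13.1 and 25.6% ± 9.78 (SD, n = 6), with adjusted exact permutation p-values of 0.889 and 0.430. Of the 9 classes, 3 rose in rate in pol1-L868M, 5 in pol2-M644G and 2 in pol3-L612M, and none fell. The log2 increases in pol1-L868M were 1.64 for A:T to G:C, 1.54 for G:C to A:T and 1.52 for A:T to T:A. In pol2-M644G the 4 largest were 4.14 for A:T to T:A, 1.64 for A:T to G:C, 1.504 for G:C to A:T and 1.13 for G:C to T:A. The increases in pol3-L612M were 3.77 for A:T to G:C and 2.99 for G:C to A:T.

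Without Msh2, transitions took the largest share wherever a polymerase was altered. In pol2-M644G msh2- isolates, G:C to A:T made up 47.5% ± 1.63 and A:T to G:C 21.2% ± 1.98 (SD, n = 4), and the share of A:T to T:A was 5.32% ± 0.717. The rate of A:T to T:A in pol2-M644G still rose 6.39-fold on MMR loss (95% interval 5.40 to 7.58, pooled), or 2.63 ± 0.23 on the log2 scale (SE). In pol3-L612M msh2- isolates, G:C to A:T made up 41.6% ± 3.64 and A:T to G:C 37.0% ± 4.39 (SD, n = 4). Those of pol1-L868M had 41.8% ± 7.31 of G:C to A:T, 24.3% ± 6.65 of G:C to T:A and 15.0% ± 3.18 of A:T to G:C (SD, n = 7). In msh2- isolates with wild-type polymerases, 1-base deletions made up 69.8% ± 8.62 (SD, n = 5).

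Against wild-type polymerases in msh2- isolates, 6 of the 9 classes rose in pol1-L868M, 6 in pol2-M644G and 7 in pol3-L612M, and none fell. The log2 increases in pol1-L868M were led by 5.30 for G:C to A:T, 5.08 for G:C to T:A, 4.33 for A:T to C:G and 4.22 for A:T to G:C. For pol2-M644G they were led by 6.16 for G:C to A:T, 5.55 for A:T to T:A, 5.40 for A:T to G:C and 4.72 for G:C to T:A. The leading increases in pol3-L612M were 6.89 for A:T to G:C, 6.66 for G:C to A:T, 4.58 for A:T to C:G and 4.53 for A:T to T:A. Adjusted exact permutation p-values of these named classes were 0.00455 for pol1-L868M and 0.0129 for the others, over 99 tests.

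On loss of Msh2, 7 of 9 classes rose with wild-type polymerases and 9 of 9 rose in each altered polymerase. With wild-type polymerases the log2 increases were led by 7.40 for 1-base deletions, 4.09 for other events, 3.59 for G:C to A:T and 3.24 for A:T to G:C. In pol1-L868M they were led by 7.35 for 1-base deletions, 7.35 for G:C to A:T, 7.32 for G:C to T:A and 5.81 for A:T to G:C. In pol2-M644G the leading values were 8.25 for G:C to A:T, 7.32 for 1-base deletions, 6.99 for A:T to G:C and 6.51 for G:C to T:A. In pol3-L612M they were 8.77 for 1-base deletions, 7.26 for G:C to A:T, 6.39 for 1-base insertions and 6.36 for A:T to G:C. Adjusted exact permutation p-values of the named classes were 0.00405 for wild type and pol1-L868M and 0.00455 for pol2-M644G and pol3-L612M. The pseudocount of 1 lowers the increase of classes with few MMR-proficient mutations, so this order of classes is not one of raw folds. In MMR-proficient isolates, 1-base deletions numbered 0 in wild type, 0 in pol1-L868M, 5 in pol2-M644G and 2 in pol3-L612M. There, 1-base insertions in pol3-L612M numbered 2. Within 1 processing set, 0 classes passed for pol1-L868M, whose 2 msh2- isolates were too few for a class to pass after adjustment. The log2 increases of its named classes were 5.56 to 7.22, each at an adjusted exact permutation p of 0.0689. For pol3-L612M the increases were 5.73 to 8.79, with 1 msh2- isolate, too few for any class to pass.

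**Figure D2:**
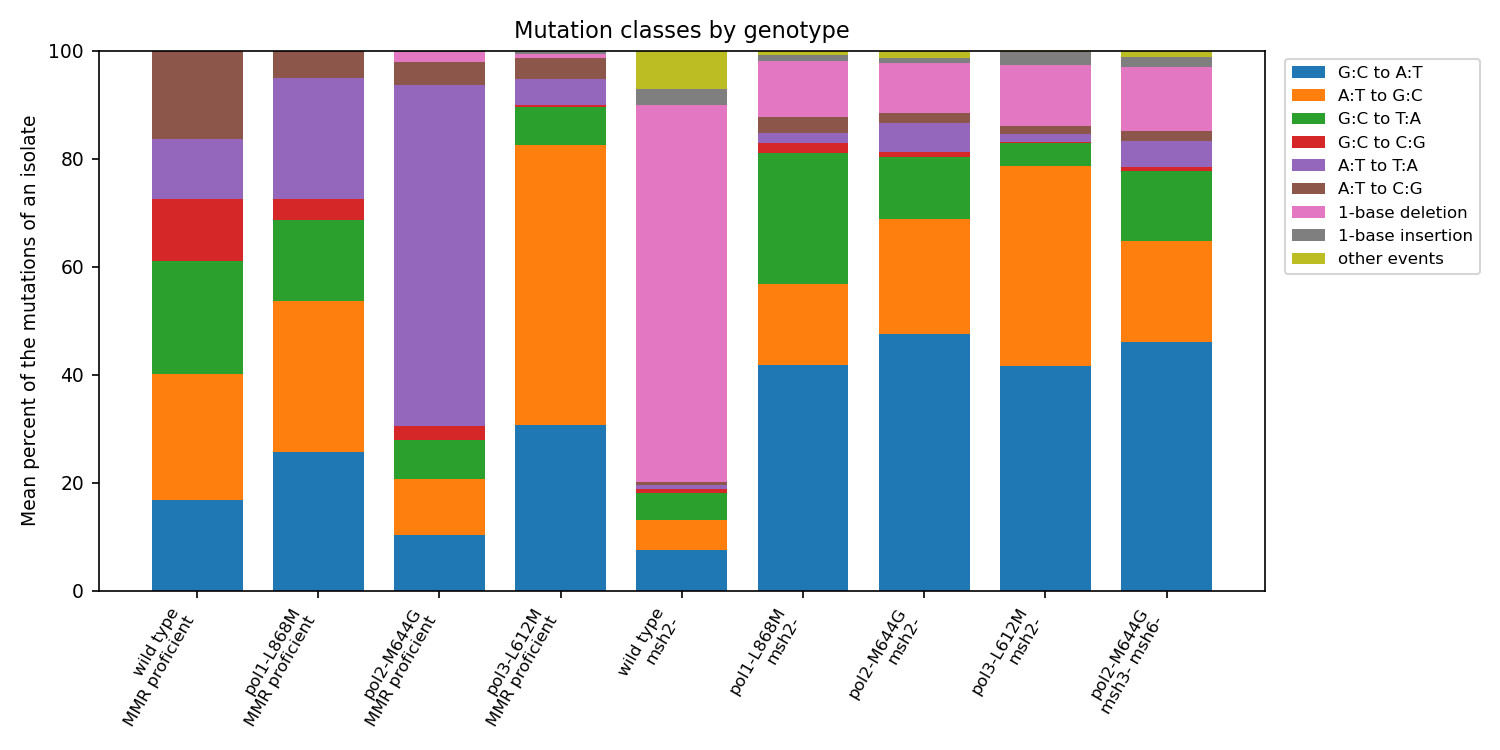
Mean percent of an isolate's mutations in each of 9 classes, as stacked bars for the 9 groups. A:T to T:A takes 63.1% in MMR-proficient pol2-M644G and 5.32% in its msh2- isolates, and 1-base deletions take 69.8% in wild-type polymerase msh2- isolates.

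Origins divide the genome into stretches in which the leading strand, copied mainly by polymerase epsilon, and the lagging strand, copied by polymerases alpha and delta, lie on opposite strands. In msh2- isolates, 5 of the 6 substitution classes had mean log2 odds of opposite sign around origins in pol2-M644G and pol3-L612M. The log2 odds for A:T to G:C were 1.27 ± 0.31 (SD, n = 4) in pol2-M644G and -2.78 ± 0.28 (SD, n = 4) in pol3-L612M. For G:C to T:A they were 1.33 ± 0.54 and -2.61 ± 0.64, for A:T to C:G 2.13 ± 0.94 and -2.37 ± 0.63, and for G:C to C:G -1.66 ± 1.00 and 1.07 ± 0.97. The last value rests on 15 substitutions, with none in replicate 2, whose log2 odds came from the 0.5 added to each cell. G:C to A:T was strongly biased in pol3-L612M, at 2.66 ± 0.27, and hardly in pol2-M644G, at -0.22 ± 0.09, although it was the most frequent class there. A:T to T:A leaned the same way in both, at 2.82 ± 0.98 and 1.68 ± 0.73. The bias of pol1-L868M lay on the side of pol3-L612M in all 6 classes, as in 1.37 ± 0.66 for G:C to A:T, -2.63 ± 0.50 for G:C to T:A, 3.13 ± 1.61 for G:C to C:G, -1.81 ± 0.54 for A:T to G:C and -3.14 ± 1.39 for A:T to C:G (SD, n = 7). For A:T to T:A its value was 0.48 ± 0.94, and -0.14 when only the 0.25 of the inter-origin distance nearest to an origin was used.

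Between pol2-M644G and pol3-L612M, 5 of the 6 classes reached the smallest exact permutation p, 0.0286, which became 0.0571 after adjustment over 18 tests. For A:T to T:A the difference was 1.14, with an adjusted exact permutation p of 0.147. A joint test over the 6 classes, added after the data were seen, gave an exact permutation p of 0.0286 for pol2-M644G against pol3-L612M. Wild-type msh2- isolates held only 13 A:T to T:A, 9 A:T to C:G and 4 G:C to C:G substitutions, and replicate 5 held 0 of the first 2 classes, so its log2 odds there came from the 0.5 added to each cell. A joint test over the 3 classes present in every msh2- isolate gave adjusted exact permutation p-values against wild type of 0.0343 for pol2-M644G, 0.0556 for pol3-L612M and 0.0343 for pol1-L868M, and of 0.00909 for pol1-L868M against either of the others. Single classes under the threshold against wild type were A:T to T:A, by 3.61, and A:T to C:G, by 3.55, in pol2-M644G and A:T to T:A, by 2.46, in pol3-L612M, each at an adjusted exact permutation p of 0.0476. They rest on these few wild-type substitutions and are not taken as differences. With isolates left out in turn, they stayed under the threshold only without replicate 2 or 3 of the wild-type msh2- isolates. Without any other isolate of the groups compared they were lost, at adjusted exact permutation p-values of 0.0571 to 0.0735. Over all isolates left out the differences were 3.27 to 4.05, 3.11 to 3.90 and 2.21 to 2.79. With an isolate fewer the smallest possible p is higher, so this loss alone does not show a smaller difference. All pol2-M644G isolates were in another processing set than all wild-type msh2- isolates, so for this pair the set and the group cannot be told apart. For pol3-L612M, the A:T to T:A difference from wild type within 1 set was 2.21, which fell short at an adjusted exact permutation p of 0.214.

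The bias changed gradually from 1 origin to the next. In pol3-L612M msh2- isolates, the G to A form of G:C to A:T fell from 84.6% (Wilson 95% interval 81.3 to 87.4) in the tenth of the distance beside the left origin to 11.9% (9.41 to 14.9) beside the right origin. Its A to G form of A:T to G:C rose from 11.8% to 87.6%. In pol2-M644G, the A to T form of A:T to T:A fell from 94.0% to 20.4%, and the A to G form of A:T to G:C fell from 68.8% to 37.2%. With MMR intact, the main class of each leaned the same way as without Msh2: 2.05 ± 1.41 for A:T to T:A in pol2-M644G and -3.72 ± 0.96 for A:T to G:C in pol3-L612M (SD, n = 8), in 8 of 8 isolates each. The exact sign-flip p was 0.00781 for both and 0.121 after adjustment over all classes and groups. For pol3-L612M it treats as separate the isolates that shared substitutions. In other frequent classes, G:C to A:T was 0.07 ± 2.89 in MMR-proficient pol3-L612M (SD, n = 8), and in MMR-proficient pol2-M644G A:T to G:C was -0.44 ± 1.65 and G:C to A:T 1.92 ± 2.12 (SD, n = 8). The changes on MMR loss in these 3 had adjusted exact permutation p-values of 0.140, 0.126 and 0.126, so a change was not detectable.

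**Figure D3:**
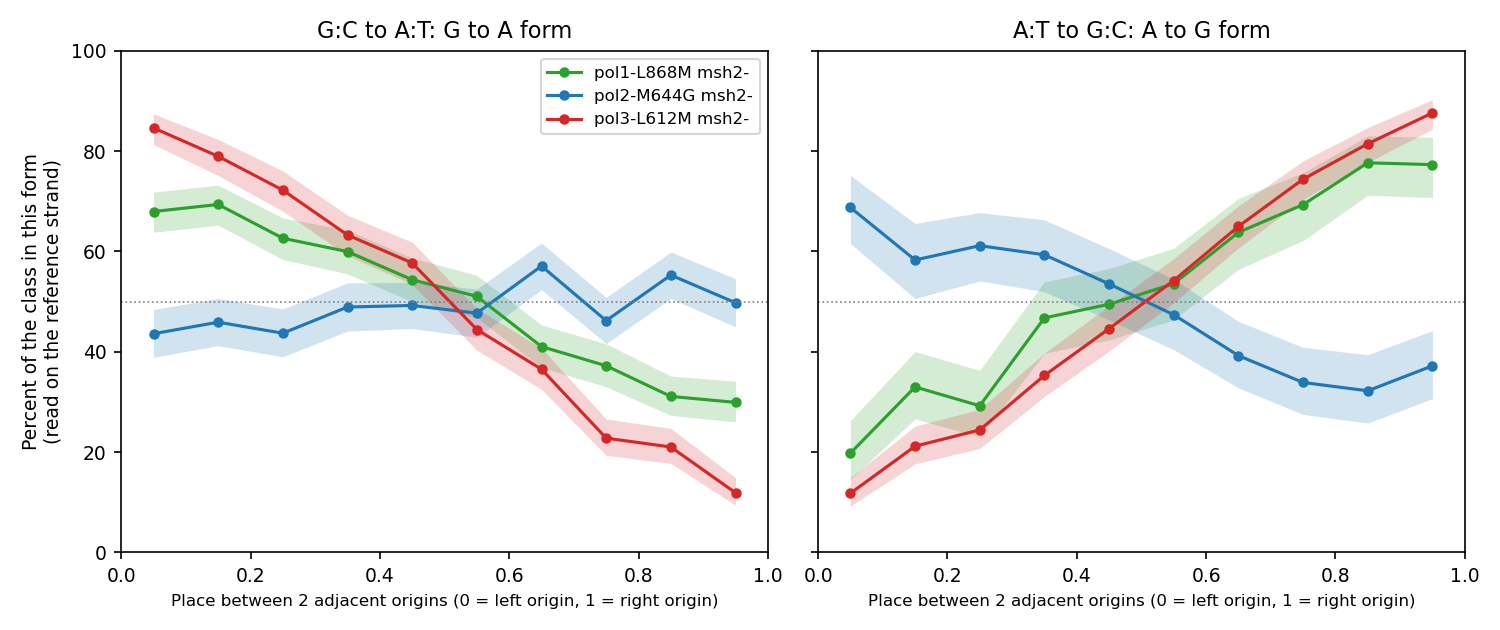
Percent of G:C to A:T substitutions in the G to A form (left) and of A:T to G:C in the A to G form (right), read on the reference strand, by place between adjacent origins in msh2- isolates of pol1-L868M, pol2-M644G and pol3-L612M; lines are pooled percents and bands are Wilson 95% intervals. In pol3-L612M the G to A form runs from 84.6% to 11.9%, while in pol2-M644G it runs from 43.6% to 49.8%.

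Insertions and deletions of MMR-deficient isolates were less dense in nucleosome cores than in linkers. Cores made up 54.0% of the genome and linkers 40.9%, yet 2325 of these events lay in cores and 3508 in linkers, a core density 0.503 of the linker density. The mean log2 ratio was -1.08 ± 0.43 (SD), below 0 in 22 of 22 isolates, with a permutation p of 1e-05, the smallest that the resamples can give. By group it was -1.62 with wild-type polymerases, -1.02 in pol1-L868M, -1.05 in pol2-M644G, -0.77 in pol3-L612M and -0.62 in the msh3- msh6- isolates. No group passed alone, with adjusted exact p-values of 0.117 to 0.577, although each unadjusted p was the smallest that 2 to 7 isolates can give. Run lengths of A and T could not be compared between cores and linkers. Cores and linkers were also not compared separately within coding and non-coding sequence. The coding density of these events was 0.167 of their non-coding density, so an effect of nucleosomes cannot be told apart from that of coding sequence.

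Substitutions differed little in density between cores and linkers. The mean log2 ratio was 0.07 ± 0.17 in the 22 MMR-deficient isolates (SD), above 0 in 18 of them, with a permutation p of 0.0647. With a 50 bp core it was 0.10, at a permutation p of 0.00212, and with no linker limit 0.20, at 4e-05. Without the limit, the linker also took in the 5.09% of the genome beyond 250 bp from a centre, where few substitutions were listed. Whether variants could be called there is not known, so the 0.20 does not compare cores with linkers alone. It was 0.09, at a p of 0.00532, without replicate 4 of the wild-type msh2- isolates, 0.08, at 0.0473, without their replicate 3 and 0.08, at 0.0315, without their replicate 5. Pooled per polymerase, the core to linker ratio was higher in msh2- than in MMR-proficient isolates by 0.86 with wild-type polymerases, 0.25 in pol1-L868M, 0.32 in pol2-M644G and 0.32 in pol3-L612M. The mean difference of 0.44 had a permutation p of 0.00223 in a test added after the data were seen. This mean weights the 4 polymerases equally and is lifted by wild type, whose MMR-proficient isolates held only 12 core and 16 linker substitutions. The test also treats as separate the MMR-proficient pol3-L612M isolates that shared substitutions. In the tests fixed beforehand, with isolates weighted equally within a polymerase, no comparison passed, and adjusted exact permutation p-values were 0.283 to 0.511.

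**Figure D4:**
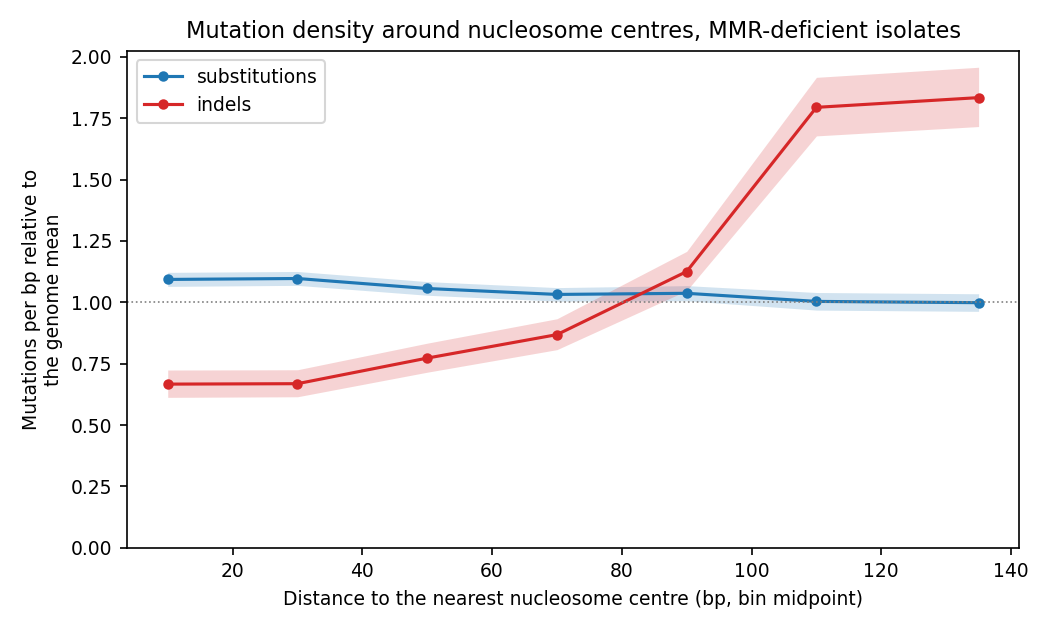
Mutations per bp relative to the genome mean by distance in bp to the nearest nucleosome centre, pooled over 22 MMR-deficient isolates; bands are 95% intervals for counting error. Insertions and deletions rise from 0.667 within 20 bp to 1.83 at 120 to 150 bp, while substitutions go from 1.09 to 0.999.

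Insertions and deletions were also sparse in coding sequence, which made up 71.9% of the genome. Their coding density was 0.167 of the non-coding density over the MMR-deficient isolates. The mean log2 ratio was -2.91 ± 0.87 (SD), below 0 in 22 of 22 isolates, with a permutation p of 1e-05, again the smallest possible. The percent that lay in coding sequence was 15.4% with wild-type polymerases, 23.7% in pol1-L868M, 32.7% in pol2-M644G, 29.6% in the msh3- msh6- isolates and 40.3% in pol3-L612M. Substitutions of the altered polymerases followed the genome more closely, with 73.5% to 74.8% in coding sequence, and those of wild-type msh2- isolates had 69.2%. Over the 22 isolates the log2 ratio of substitutions was 0.07 ± 0.25 (SD), at a permutation p of 0.201, and without replicate 5 of the wild-type msh2- isolates it was 0.11, at 0.0148. In the comparison fixed beforehand of msh2- with MMR-proficient isolates, no polymerase passed, with adjusted exact permutation p-values of 0.131 to 0.735. The lowest was for insertions and deletions of pol2-M644G, with a log2 difference of -1.89, and without replicate 1 of its MMR-proficient isolates the difference was -2.23, at 0.0152. Those MMR-proficient isolates held only 6 such events, 5 coding and 1 non-coding, and no isolate held more than 1. Their log2 ratios, with a mean of -0.57, were therefore set largely by the value added to each cell. For this reason the difference does not measure a change on MMR loss.

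No gene passed the test for more substitutions than its length predicts in MMR-deficient isolates. Of 5860 genes, 0 passed after adjustment in the exact binomial test and 306 had an unadjusted p under 0.05, although only 2% of simulated genes at 2-fold and 56% at 4-fold were called. For insertions and deletions 11 genes passed and 198 had an unadjusted p under 0.05. Among them were BNA6, which makes a pyridine nucleotide precursor, with 5 events against 0.180 expected, and MUD1, a U1 small nuclear ribonucleoprotein component, with 5 against 0.182 (both adjusted p 0.00166, 5 isolates). RRP8, a ribosomal RNA methyltransferase, had 5 against 0.239 (0.00443) and SEM1, a component of the proteasome lid, 3 against 0.0547 (0.0153). The other named genes were YCR095W-A with 4 against 0.0322 (0.000255), YLR412C-A with 4 against 0.0419, YMR030W-A with 4 against 0.0590, YGR273C with 4 against 0.106, YDL027C with 5 against 0.256 and YPL119C-A with 3 against 0.0535. When variants listed in more than 1 isolate were left out, 0 of these genes passed. The ratio of observed to expected was then 0 for YCR095W-A and YDL027C, and it fell in the others, to between 6.48 for MUD1 and 28.1 for YLR412C-A. This setting also drops a change that arose separately at the same site in several isolates, so it cannot tell recurrence from shared descent. Expected values rest on coding length alone and take no account of A and T runs. With isolates hit counted in place of mutations, YGR273C also fell short, at a ratio of 28.8 and an adjusted exact p of 0.0926.

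In MMR-proficient isolates 5 genes passed for substitutions and 86 had an unadjusted p under 0.05. TAF1, a subunit of the general transcription factor TFIID, had 5 against 0.195 expected (adjusted p 0.00576), and TIP20, which acts in retrograde vesicle transport, had 4 against 0.128 (0.0197). YNL162W-A had 3 against 0.0133, OPI10 3 against 0.0452 and YKL023W 3 against 0.0508. Without variants listed in more than 1 isolate, which include those shared by the related pol3-L612M isolates, 0 genes passed, and the ratio fell to 0 for YNL162W-A and OPI10, 9.64 for TIP20, 19.0 for TAF1 and 24.3 for YKL023W. For the 6 insertions and deletions in genes 0 genes passed, and 6 had an unadjusted p under 0.05.

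Replication genes held fewer substitutions than their length predicts in MMR-deficient isolates, short of the threshold. The 17 genes of the replication polymerase list held 76 against 100.3 expected, a ratio of 0.758 (95% interval 0.597 to 0.949), with an adjusted exact p of 0.0564. This list also holds POL30 and RFC1 to RFC5, the genes of the sliding clamp and its loader, which are not polymerases. POL1 had 10 against 13.6, POL2 10 against 20.5, POL12 7 against 6.52 and PRI2, a primase subunit, 8 against 4.89, and POL3 had 6 against 10.1. The 8 mismatch repair genes held 59 against 58.5, with MSH6 at 17 against 11.5, PMS1 at 10 against 8.07, MLH2 at 8 against 6.43 and MLH3 at 6 against 6.61. The 9 checkpoint genes held 110 against 105.4, with the checkpoint kinases MEC1 at 31 against 21.9 and TEL1 at 20 against 25.7, RAD9 at 13 against 12.1 and LCD1, the partner of Mec1 also called DDC2, at 12 against 6.91.

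Genes of signalling and chromatin followed their length. The 14 genes of cyclic AMP and RAS signalling held 125 substitutions against 135.7, with the RAS inhibitors IRA2 at 29 against 28.4 and IRA1 at 20 against 28.6, adenylate cyclase CYR1 at 19 against 18.7 and CDC25 at 17 against 14.7. The 9 chromatin remodelling genes held 124 against 110.9, with the remodelling ATPases SNF2 at 25 against 15.7, CHD1 at 22 against 13.6, SWR1 at 12 against 13.99 and ISW1 at 14 against 10.4. The 8 large genes held 255 against 237.7, with MDN1 at 58 against 45.4, DYN1, the heavy chain of dynein, at 39 against 37.8, FAB1, a lipid kinase, at 33 against 21.0 and TRA1 at 35 against 34.6. The 8 reporter and marker genes held 41 against 37.1, with LYS2 at 16 against 12.9, CAN1 at 8 against 5.46, ADE2 at 5 against 5.28 and HIS7 at 5 against 5.10. For these 4 lists and for mismatch repair and checkpoint the ratios were 0.921 to 1.12 and adjusted exact p-values were 0.508 or above. Adjusted over the list alone, 0 members of any list passed for these substitutions, as over all genes tested.

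The cell wall genes with internal repeats were the only list that passed for substitutions in MMR-deficient isolates, with 95 against 130.6 expected, a ratio of 0.727 (95% interval 0.589 to 0.889) and an adjusted exact p of 0.0107. The deficit lay in FLO1, FLO5, FLO9 and FLO10, the flocculin genes, which are similar to each other in sequence and listed 0 substitutions against 44.7 expected. Whether variants in these genes could be called at all is not in the files. The other 10 members held 95 against 85.9, a ratio of 1.11 with an unadjusted exact p of 0.330. Of those, FIG2 had 20 against 14.9, HKR1 17 against 16.7, MUC1, the gene also called FLO11, 16 against 12.6 and DAN4 11 against 10.7. For insertions and deletions no list passed, and the largest ratio was 1.78 for chromatin remodelling, with 13 against 7.30 and an adjusted exact p of 0.376. HKR1 had 5 insertions or deletions against 1.10 and FAB1 6 against 1.39. Adjusted over the list alone, 1 large gene passed for insertions and deletions, and over all genes tested 0 did. In MMR-proficient isolates no list passed for substitutions, where mismatch repair genes held 4 against 1.16 at an adjusted exact p of 0.241, or for insertions and deletions, where checkpoint genes held 1. Adjusted over the list alone, 1 chromatin remodelling gene passed for substitutions and 1 checkpoint gene for insertions and deletions, and over all genes tested 0 did.

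Of the genes altered by design, MSH2 held 1 mutation in msh2- isolates against 2.75 expected, over only 943 bp annotated as MSH2. In msh3- msh6- isolates MSH3 and MSH6 held 0, against 1.11 and 1.36. POL2 held 0 in pol2-M644G msh2- isolates against 5.09 expected (unadjusted exact p 0.00616), and the same isolates also held 0 in POL1 against 3.36 (0.0346) and in POL3 against 2.51 (0.0810), which were not altered there. POL1 held 7 in pol1-L868M msh2- isolates against 4.53, and POL3 held 3 in pol3-L612M msh2- isolates against 3.57.

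Nearly all mutations were heterozygous. Homozygous variants numbered 299, and by isolate they made up 0.654% ± 0.525 (SD, n = 5) in wild-type msh2- isolates and 0.692% ± 0.742 (SD, n = 7) in pol1-L868M msh2- isolates, against 0% in the MMR-proficient isolates of both, at adjusted exact permutation p-values of 0.0256. In MMR-proficient isolates an isolate's few mutations could not show shares this small. In pol2-M644G the share was 0.237% ± 0.112 (SD, n = 4) against 5.80% ± 4.54 (SD, n = 8), with an adjusted exact permutation p of 0.0620, and in pol3-L612M it was 0.939% against 1.67%, with one of 0.743. Chromosome 1 of replicate 4 of the pol3-L612M msh2- isolates held 26 homozygous variants of 30, and that of replicate 5 of the pol1-L868M msh2- isolates held 25 of 32.

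Mutations were spread over the 16 chromosomes close to their lengths. In MMR-deficient isolates the ratio of observed to expected lay between 0.928 for chromosome 1 and 1.12 for chromosome 9. Over all 52 isolates the mean log2 ratio was -0.51 for chromosome 12 and -0.28 for chromosome 10, with adjusted permutation p-values of 0.00032 and 0.0301, and no chromosome departed by more than 1.5 times. That mean weights isolates with few mutations as much as those with many. It was below 0 on all 16 chromosomes, so a test of it against 0 is biased towards a deficit. Pooled over MMR-deficient isolates the ratios of chromosomes 12 and 10 were 0.936 and 1.007.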

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

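The tests of explanations for the spread of pol1-L868M msh2- isolates in this part were chosen only after the result was seen, and the depth test replaced a first one that had decided nothing. Extreme isolates were sought in 74 groups and values, and 3 were found, while chance finds about 1 in 20, or 3.7. Replicate 1 of the MMR-proficient wild-type isolates lay far below the others, at -4.95 on the log2 scale for mutations per passage and, since its only mutation was a substitution, at -4.95 for substitutions, against -3.37 to -2.15 in the other 7. Replicate 4 of the pol1-L868M msh2- isolates had an origin asymmetry of 0.023 for G:C to A:T, against 1.25 to 2.01 in the other 6.

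Folds on MMR loss for substitutions differed from that of wild-type polymerases by 2.93 in pol1-L868M, 2.25 in pol2-M644G and 2.86 in pol3-L612M on the log2 scale, by a permutation test of the difference. For pol2-M644G the processing set and the group cannot be told apart. Origin asymmetry differed between pol2-M644G and pol3-L612M msh2- isolates by -2.88 for G:C to A:T, 3.94 for G:C to T:A, 4.05 for A:T to G:C and 4.50 for A:T to C:G. In these 4 classes every isolate of pol2-M644G lay on 1 side of 0 and every isolate of pol3-L612M on the other, and each difference had an adjusted exact permutation p of 0.0571.

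Substitution rates of the 7 pol1-L868M msh2- isolates spanned 19.8 to 148.8 per passage, an SD of 0.913 on the log2 scale, against 0.308 for insertions and deletions. Missed variants at low depth would have lowered both kinds together, and more cell divisions per passage would have raised both. The slope of insertions and deletions on substitutions was 0.083 ± 0.15 (SE, log2 on log2), which argues against either as the whole cause, although without replicate 3 it was 0.058 ± 0.25. An unrecognised pol3-L612M allele is argued against by the share of G:C to T:A among substitutions, which was 25.3% or above in the 3 isolates with the highest rates and 3.71% to 7.27% in pol3-L612M msh2- isolates. Among the 5 isolates of 1 processing set the SD was 0.818, and it rested on replicate 3, since the other 4 had 0.152. Those 4, replicates 4 to 7, had 23 labelled passages and rates of 38.6 to 49.4. Replicates 1 to 3, at 19.8, 79.5 and 148.8, had 31, so the wide spread lay among the 31-passage isolates. Whether the number of passages matters was not tested. No biological explanation was tested, and other mutations acquired in single lines could account for the spread and stay open.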

How the results depend on the processing

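The tests of processing sets, depth, related isolates, all MMR-deficient isolates together and the shortened cell wall list were chosen only after the result was seen. No paired analysis was possible because isolates with the same replicate number were separate lines. Not run were homopolymer runs and their classes moved by 1 base, for lack of a genome sequence, the better-supported nucleosomes, for lack of a score, and subtraction of 1-passage isolates, which listed 0 variants. The MMR-proficient wild-type values rest on 1 to 7 mutations an isolate, and the lowest median coverage of an isolate was 45.5. The 11 total rates kept their direction and side of the threshold with 1 passage subtracted, arithmetic means, clustered variants counted once and a coverage of at least 100. They also did so with related isolates counted as 1, which can change only the comparisons that use MMR-proficient pol3-L612M isolates. With isolates left out in turn, 1398 of 1452 values kept both, 22 reversed, 11 passed newly and 21 fell short. Except where a reason is given, the cause was not tested.

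With 31-passage isolates only, which left 1 to 4 msh2- isolates a group, the log2 differences of pol1-L868M, pol2-M644G and pol3-L612M from wild type in msh2- fell short at 2.87, 3.38 and 3.89, as did MMR loss in pol3-L612M at 6.88. So few isolates could not have passed after adjustment. The pol2-M644G difference in the fold on MMR loss, 0.03 for all mutations, took either sign: -0.12 with 31 passages, -0.15 with variants within 10 bp counted once, -0.055 with msh3- msh6- isolates added, -0.092 with coverage of at least 100, and -0.26 to 0.27 with isolates left out. With substitutions only, the differences in this fold passed at 2.93, 2.25 and 2.86 for pol1-L868M, pol2-M644G and pol3-L612M, and with variants listed in 1 isolate only that of pol3-L612M passed at 2.53. With insertions and deletions only, pol3-L612M against wild type fell short at 0.45 with MMR, as did pol1-L868M at 0.0034 and pol2-M644G at 0.63 without Msh2, and msh3- msh6- against msh2- reversed to 0.17. Within 1 processing set, MMR loss fell short at 6.69 in pol1-L868M, and 0 classes passed there, with 2 msh2- isolates, too few to pass after adjustment. In pol3-L612M it was 6.88, with 1 msh2- isolate, too few for the total or any class to pass.

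For origin asymmetry against wild type, the 3 single classes under the threshold, A:T to T:A and A:T to C:G in pol2-M644G and A:T to T:A in pol3-L612M, fell short within 10 kb (4.46, 4.31 and 2.00) and in the 0.25 of the inter-origin distance nearest to an origin (4.63, 4.76 and 3.70). Within 1 processing set the last fell short at 2.21. With isolates left out they were 3.27 to 4.05, 3.11 to 3.90 and 2.21 to 2.79. Of the isolates left out, only without replicate 2 or 3 of the wild-type msh2- isolates did other classes pass, with ranges over all of them: in pol2-M644G G:C to A:T (-2.19 to -1.39), G:C to C:G (-2.09 to -1.27) and A:T to G:C (2.04 to 2.83, and 2.82 with 1 kb around origins left out), and in pol3-L612M G:C to T:A (-3.49 to -2.24) and A:T to G:C (-2.01 to -1.22). G:C to C:G of pol3-L612M reversed within 10 kb (-0.13). G:C to T:A in wild-type msh2- isolates, 0.11, reversed within 10 kb (-1.23), in that nearest 0.25 (-1.13), with 1 added (-0.15) and with isolates left out (-0.37 to 0.88), and A:T to T:A in pol1-L868M reversed in that nearest 0.25 (-0.14).

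Core against linker substitutions in all 22 MMR-deficient isolates passed with a 50 bp core (0.10), with no linker limit (0.20, with bases far from any centre taken in) and without replicate 3, 4 or 5 of the wild-type msh2- isolates only (0.055 to 0.094 over all isolates left out). In wild-type msh2- isolates the ratio reversed (0.045, 0.052 and, with isolates left out, -0.19 to 0.020). For insertions and deletions of pol2-M644G it reversed with a 50 bp core in MMR-proficient isolates (0.044), and the change on MMR loss reversed with no linker limit (0.094) and with isolates left out (-0.25 to 0.25).

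Coding against non-coding substitutions in all 22 passed with the outer 20 kb left out (0.094) and, of the isolates left out (0.057 to 0.11), only without replicate 5 of the wild-type msh2- isolates. In MMR-proficient pol2-M644G they reversed (-0.0047, and -0.14 to 0.14 with isolates left out), as did their change on MMR loss in pol1-L868M (-0.27 to 0.11), and the change for insertions and deletions in pol2-M644G passed (-2.06) and, of the isolates left out (-2.23 to -1.53), did so only without MMR-proficient replicate 1. The MMR-proficient pol2-M644G isolates held too few insertions and deletions for this to measure a change. With variants listed in 1 isolate only, 0 genes passed for insertions and deletions of MMR-deficient isolates and 0 for substitutions of MMR-proficient isolates. YCR095W-A, YDL027C, YNL162W-A and OPI10 had a ratio of 0, since their variants were all listed in more than 1 isolate. The other named genes fell to 6.48 to 28.1. This setting cannot tell recurrence at a site from shared descent. With isolates hit in place of mutations, YGR273C fell short at 28.8. The cell wall list reversed to 1.11 without FLO1, FLO5, FLO9 and FLO10.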

Other observations

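All tests of explanations in this part were chosen only after the result was seen. The isolate with no passage number listed 0 variants. Of the 72 labelled isolates, it and the 19 1-passage isolates gave no value for any comparison.

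Replicates 2, 6 and 7 of the MMR-proficient pol3-L612M isolates shared 43 substitutions between at least 2 of them, of which 19 were in all 3 and 18 only in replicates 6 and 7. Recurrent calling errors are argued against, since 0% of the 43 were listed in any of the other 49 isolates. Variants of a starting clone of these 3 lines alone would also be absent from the others. The list holds 0 variants for 1-passage isolates, so this test cannot decide on variants of the starting strain. Mixing of DNA between libraries is argued against by the allele shares, as the lowest median percent of reads with the new allele at the shared substitutions was 49.01, near that of a heterozygous variant. Passages shared before the lines were parted may explain the pattern, but 6 substitutions were shared by replicate 2 with only 1 of the others, which a simple branching of the lines would not give, so this stays open. Each isolate also listed substitutions of its own, 6 in replicate 2, 4 in replicate 6 and 5 in replicate 7, so they were not the same isolate deposited again.

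Chromosome 1 variants were mostly homozygous in replicate 4 of the pol3-L612M msh2- isolates (86.7%) and in replicate 5 of the pol1-L868M msh2- isolates (78.1%). Mapping problems on chromosome 1 or the authors' filter are argued against by the 19 other MMR-deficient isolates with at least 5 variants on chromosome 1, whose median was 0%. Coverage of chromosome 1, against the trend of the other chromosomes with length, was 0.467 in the first and 0.448 in the second, so loss of 1 copy of chromosome 1 is a candidate explanation for both. In the others it was 0.101 to 1.08, and the lowest, replicate 3 of the wild-type msh2- isolates, had only 2 of 11 variants listed as homozygous, so low coverage alone does not mark the pattern. Other isolates had homozygous variants along part of a chromosome, such as 75 of 327 on chromosome 16 of replicate 1 of the pol3-L612M msh2- isolates, between positions 18020 and 305477, at a relative coverage of 0.988.

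A hypothesis concerns 1-base deletions of A against T around origins in msh2- isolates: slippage on the strand that the altered polymerase copies would give pol2-M644G and pol3-L612M opposite signs. The log2 odds were 0.88 ± 0.43 (SD, n = 4) in pol2-M644G and -0.80 ± 0.20 (SD, n = 4) in pol3-L612M, and in the pol2-M644G msh3- msh6- isolates they were 0.51 ± 0.77 (SD, n = 2), with opposite signs in the 2. The difference of 1.68 ± 0.24 (SE) had an exact permutation p of 0.0286, the smallest possible, and the isolates lay between 0.397 and 1.43 and between -1.07 and -0.637. Isolates with wild-type polymerases, at 0.55, and pol1-L868M, at 0.24, had the sign of pol2-M644G. In pol1-L868M this was so although its substitutions lay on the side of pol3-L612M in the classes where pol2-M644G and pol3-L612M had opposite signs. The hypothesis may therefore hold for some deletions only, and the lengths of A and T runs were not in the files.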
